A study of Drosophila melanogaster with 4 samples.

How the data were processed

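ChIP-seq was performed on formaldehyde-fixed, sonicated chromatin of unstaged wild-type embryos, per the labels' protocols, with 4 libraries (input, CTCF, H3 and H2A.V), 1 of each. The H2A.V library was grouped by its antibody label, since its title names the protein differently. The input and H3 libraries were not analysed here. Reads were aligned with Bowtie 1.1.1 to dm3 and peaks were called with HOMER, per the submitters' processing notes; the HOMER version is not given in the sources used here. The sequence names in the files (2RHet, U, Uextra) are those of the release that dm3 corresponds to.

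The authors' CTCF file holds the deposited start and end of each peak in bp. Per the file headers, findPeaks was run in factor style on the CTCF tags against the input, with a peak size of 200 bp, a fragment length of 200 bp and a minimum distance of 400 bp between peaks. A peak needed at least 37 tags where 16.4 were expected, an FDR of 0.001, and a 4-fold excess with a Poisson p-value of 1e-04 over the input and over the surrounding 10000 bp. Of 18141 putative CTCF peaks, 15117 were removed against the input and 565 against the local signal, per the file headers. The H2A.V file holds regions called in histone style, per the file headers, from 500 bp windows stitched across up to 1000 bp into regions of varying width. The H2A.V threshold was 67 tags where 43.8 were expected, with a 4-fold excess over the input at the same Poisson p-value as for CTCF. The header counts 172723 putative H2A.V peaks, of which 142 were removed against the input and 0 against the local signal; the step from these to the 3229 listed regions, stitching included, is not itemised there. Stitching fills gaps between neighbouring windows, so a gap in H2A.V signal within a region is not visible in the list. The score column deposited by the authors holds 1 in every line of both files and the strand column holds a plus, so neither was used. Tag counts and fold changes per peak, which the headers name, are not among the 6 columns and were not used here. Peaks were called on single libraries and no replicate was pooled, as far as the headers tell.

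Coordinates are dm3 and are printed counting from 1. No annotation or sequence of dm3 was used here. For that reason the tests of peaks against transcription start sites, annotation classes, divergent promoters, gene lists (18 lists had been fixed) and the CTCF motif, all planned before the data were examined, were not run, and no gene is named. The planned tests of the authors' score and of strand were not run because both columns are constant, and the planned rule for naming peaks, which ranked them by score, named none; the positions printed were chosen after the values were seen.

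Overlap was counted where a CTCF peak and an H2A.V region shared at least 1 bp. The null distribution came from 10000 circular shifts of one list against the other, with 1 random offset per arm within the span from the first to the last peak of either list, which keeps the spacing of each list. P-values are two-sided and count shifts at least as far from the shift mean as the observed value. The same shifts gave the distance between midpoints and the distance from a CTCF midpoint to the nearest H2A.V edge. The 4 CTCF peaks on the sequence with no H2A.V region count as not overlapping. Even placement in regions of over 1000 bp gives each zone its share of the width of each region hit. Spacing was compared with 10000 uniform placements per arm. Arm shares were compared by Fisher's exact test with Benjamini-Hochberg adjustment over 13 sequence names. Densities use the same spans, since arm lengths were not used here, with exact Poisson intervals. X and autosomal densities were compared over 1 Mb bins with a permutation test of 100000 resamples, and widths with the same test. Shares carry 95% Wilson intervals.

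The shift test was checked on simulated lists of 2459 peaks placed against the real H2A.V regions, 50 lists per setting with 200 shifts each. Peaks not planted on a region were placed uniformly over the arm span. The check therefore does not cover CTCF peaks that cluster or that share regional density with H2A.V. With 0% planted, 3 of 50 lists had p under 0.05. With 1% planted, 32 of 50 did so, with 2% planted 48 of 50, and with 5% planted 50 of 50. With 30% planted, the excess came out as 30.2 ± 1.07% (SD over lists). The permutation test of means gave p under 0.05 in 5 of 100 data sets with no difference. Alternatives covered the overlap rule, the null placement, each arm left out in turn and, added after seeing the data, shifts of 20 to 100 kb and parts of the lists in deposited order. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.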

Results

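Chromatin from unstaged wild-type Drosophila melanogaster embryos was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in 4 libraries, namely an input, a CTCF ChIP, an H3 ChIP and an H2A.V ChIP. CTCF is a zinc-finger DNA-binding protein known as an insulator factor, and H2A.V is the histone H2A variant of the fly, known from nucleosomes at the start of active genes. Called peaks of the CTCF and H2A.V libraries were analysed here, with 1 library per antibody and no replicate. The CTCF library held 11657333 tags, of which 1235452 (10.6%) lay in peaks, or 502 tags per peak on average. The H2A.V library held 12260001 tags, of which 1297263 (10.58%) lay in its regions, or 402 tags per region. The 2459 CTCF peaks each spanned 201 bp and together covered 0.354% of the 139731881 bp genome size set at peak calling. The 3229 H2A.V regions had a median width of 1347 bp (quartiles 795 and 1964 bp, widest 9334 bp) and covered 5.08 Mb, or 3.64% of that size. All intervals given below cover counting error only. The p-values treat peaks, regions or 1 Mb bins as the units, or count random shifts or placements of a list. All of them describe these libraries and not a spread between embryo collections.

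The first comparison asked how often CTCF sites and H2A.V-marked chromatin coincided. Of the 2459 CTCF peaks, 929 (37.8%, 95% Wilson interval 35.9 to 39.7%) shared at least 1 bp with an H2A.V region, and 1530 shared none. When the same peaks were shifted around each chromosome arm, 116 ± 10.6 (SD over 10000 circular shifts) did so. The observed overlap was 8.01-fold that of shifted peaks (two-sided permutation p = 0.0001, the smallest the shifts can give). The shifts do not hold peaks to transcription start sites. How far a shared place at start sites accounts for the excess was not tested. Seen from the other list, 903 of the 3229 H2A.V regions (28.0%, 95% Wilson interval 26.4 to 29.5%) held a CTCF peak, against 114 ± 10.4 (SD) under shifts. Of these regions, 877 held 1 CTCF peak and 26 held 2. The median distance from a CTCF peak midpoint to the nearest H2A.V midpoint was 2667.5 bp, against 23421 ± 1007 bp (SD) under shifts. A total of 1033 CTCF midpoints (42.0%) lay within 1 kb of an H2A.V midpoint, 7.96-fold more than the 130 ± 11.3 (SD) of shifted peaks (permutation p = 0.0001). The H2A.V regions with a CTCF peak were wider than those without, with medians of 1488 and 1266.5 bp and a 1.21-fold ratio of geometric means (two-sided permutation test, p = 1e-05, the smallest its 100000 resamples can give). They were narrower, however, than the regions that shifted peaks hit, which had a geometric mean width of 1818 bp against 1492.5 bp observed (permutation p = 0.0005). The comparisons of width were not among the planned tests. Each list was also divided at its middle line, in deposited order, into early and late entries. Among early CTCF peaks, 13.3% overlapped an early H2A.V region, a 4.00-fold excess over shifts, and among late CTCF peaks 21.7% overlapped a late region, a 15.1-fold excess. Late H2A.V regions were narrower, with a median of 501 bp in the last of 10 equal parts against 3627 bp in the first. Shifted peaks hit them less often, so these folds have unlike bases.

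The place of CTCF peaks relative to the H2A.V regions was not even. CTCF midpoints were in excess in 2 zones, deep inside a region and around a region's edge, with a lower excess between them. The zones and their limits were not among the planned tests. Over 500 bp inside a region lay 471 CTCF midpoints, 10.5-fold more than under shifts (95% Poisson interval of the count over the shift mean, 9.56 to 11.5). At 250 to 500 bp inside lay 116, a 4.58-fold excess (3.78 to 5.49). In the last 250 bp inside the edge lay 239, a 7.31-fold excess (6.41 to 8.30), and in the first 250 bp outside it lay 270, an 8.26-fold excess (7.30 to 9.30). The excess fell to 1.82-fold (1.38 to 2.35) at 250 to 500 bp outside, where 57 midpoints lay. At 500 to 1000 bp outside, 47 midpoints were found against 56.9 under shifts, a difference that did not pass the test (permutation p = 0.198). Farther out, 167 midpoints lay at 1 to 5 kb (0.531 of the shift mean) and 1088 at over 5 kb (0.568 of it); with the total of peaks fixed, an excess near the regions lowers the counts elsewhere. In H2A.V regions of over 1000 bp alone, 106 midpoints lay in the outer 250 bp, 85 at 250 to 500 bp inside and 471 deeper, against 184, 184 and 294 under even placement in the same regions, so the inner edge was not preferred in these. In 50 bp bins, those fuller than any other within 200 bp and with over 40 midpoints held 90 CTCF midpoints at 600 to 650 bp inside, 63 at 200 to 250 bp inside and 81 at 100 to 150 bp outside. A smaller maximum of 51 lay at 750 to 800 bp inside, within 200 bp of the deepest of these. The H2A.V regions were built from 500 bp windows, and their widths came in steps, with 408 regions of the narrowest width (501 bp), 0 between 550 and 600 bp and 154 between 600 and 650 bp. The exact distances of these maxima may therefore carry the window size of the peak calling, which was not tested.

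**Figure D1:**
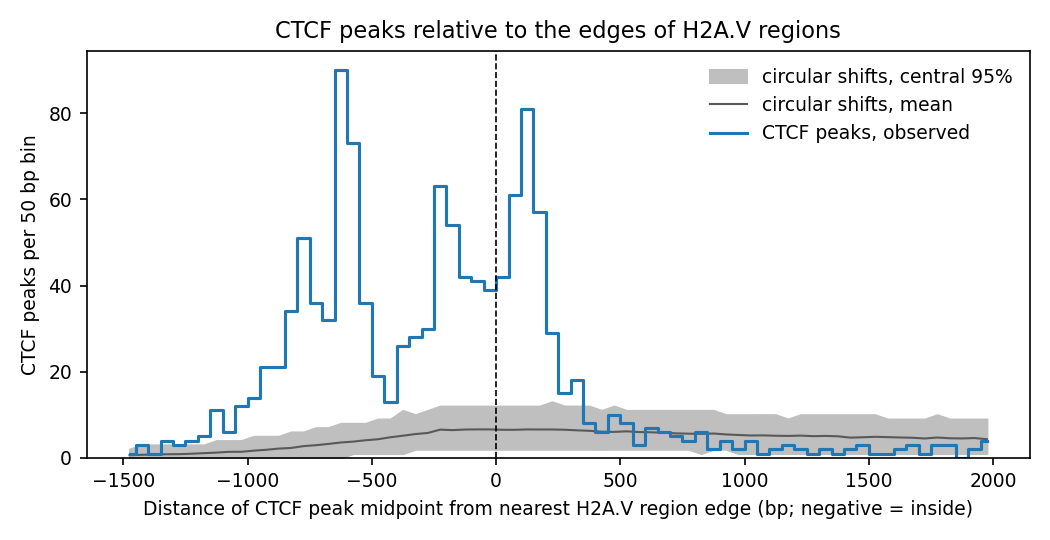
CTCF peak midpoints per 50 bp bin (blue) against their distance in bp from the nearest H2A.V region edge, negative inside a region, with the mean (dark grey) and the central 95% (light grey) of 1000 circular shifts. The bins at 600 to 650 bp inside (90 midpoints) and 100 to 150 bp outside (81 midpoints) stand far above the band.

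The share of CTCF midpoints in the central part of a region, at least 0.6 of the way from the edge to the centre, was set against the 40% that even placement gives. It was 77.8% (217 of 279, 95% Wilson interval 72.5 to 82.3%) in H2A.V regions of 1300 to 2000 bp and 52.7% (39 of 74, 41.5 to 63.7%) in those of 1100 to 1300 bp. It was 25.3% (45 of 178, 19.5 to 32.1%) in regions of 510 to 1100 bp. In regions of over 2000 bp it was 41.4% (113 of 273, 35.7 to 47.3%), and in regions of the narrowest width 40.9% (9 of 22, 23.3 to 61.3%), both with intervals that include even placement. The width classes were set after the profile had been seen, and a maximum at 600 to 650 bp from an edge is central by construction in regions of 1300 to 2000 bp.

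The next comparison was between chromosome arms. The euchromatic arms held between 17.8 CTCF peaks per Mb of span on 2L (95% Poisson interval 16.1 to 19.6) and 22.6 on the X (20.7 to 24.7). H2A.V regions ranged from 24.6 per Mb on 2L (22.6 to 26.7) to 29.9 on 2R (27.6 to 32.3). Chromosome 4, a small chromosome known for its heterochromatin-like packaging, had the highest density in both lists among the 6 arms for which densities were computed, with 35 CTCF peaks at 29.8 per Mb (20.8 to 41.5) and 50 H2A.V regions at 42.6 per Mb (31.6 to 56.2). The 7 heterochromatic and unplaced sequence names together held 35 CTCF peaks and 31 H2A.V regions. The share of CTCF peaks on an arm was compared with its share of H2A.V regions for all 13 sequence names. By Fisher's exact test, 0 of the 13 differed after Benjamini-Hochberg adjustment (lowest adjusted p = 0.151) and 3 had an unadjusted p under 0.05. On the X, CTCF peaks numbered 22.9 ± 5.23 per 1 Mb bin (SD, 22 bins) against 19.7 ± 5.71 on 2L, 2R, 3L and 3R (SD, 94 bins), a difference of 3.13 (two-sided permutation test, p = 0.0215). Without the last 245 CTCF peaks in deposited order, the difference was −1.12 (permutation test, p = 0.415); this part of the list was picked for its X share, so leaving it out lowers the difference by construction. H2A.V regions numbered 26.6 ± 9.87 per bin on the X and 26.8 ± 10.4 on the autosomal arms (permutation test, p = 0.945), and without the last of 10 equal parts of that list the X had −2.60 per bin relative to the autosomal arms (p = 0.268).

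**Figure D2:**
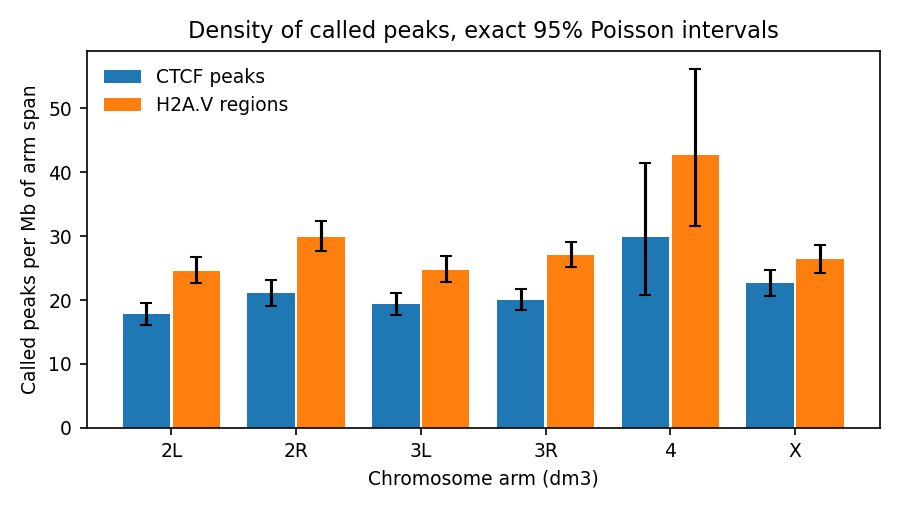
Called CTCF peaks (blue) and H2A.V regions (orange) per Mb of arm span on 6 chromosome arms in dm3 coordinates, with exact 95% Poisson intervals as error bars. Of these arms, chromosome 4 has the highest density in both lists (29.8 and 42.6 per Mb) and the widest intervals.

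CTCF peaks on the X coincided with H2A.V less often than those on the autosomes. On the X, 159 of 506 CTCF peaks (31.4%, 95% Wilson interval 27.5 to 35.6%) overlapped an H2A.V region, against 741 of 1883 (39.4%, 37.2 to 41.6%) on 2L, 2R, 3L and 3R (odds ratio 0.706, two-sided Fisher's exact test, p = 0.00112). The X share was 6.68-fold that of shifted peaks, and the shares on 2L, 2R, 3L and 3R were 8.54-fold, 7.85-fold, 8.54-fold and 8.57-fold (permutation p = 0.0001 on each). On chromosome 4, 19 of 35 CTCF peaks (54.3%, 38.2 to 69.5%) overlapped, 6.51-fold more than under shifts (permutation p = 0.0004). The X share was the lower one in 8 of 10 equal parts of the CTCF list. It was the higher one in part 2 (17.5% against 14.5%) and in part 10, which held 119 of the 506 X-linked peaks (42.0% against 37.0%, Fisher's exact test, p = 0.498). This comparison of the X with the autosomes was added after the lists had been seen. It also depends on which H2A.V regions were listed on the X. Of the H2A.V regions on 2L, 2R, 3L, 3R and X, the X held 14.4% among early entries. It held 33.1% in the last of 10 equal parts, against 18.8% of the span. The density of all listed regions was alike, at 26.6 per Mb on the X and 26.8 on the autosomal arms. Whether weaker H2A.V calling on the X lowered the overlap there was not tested.

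H2A.V regions clustered along the arms far more than CTCF peaks did. Neighbouring H2A.V regions had a median spacing of 10121 bp between midpoints, 0.389 of the 26017 ± 478 bp (SD) of uniformly placed regions (permutation p = 0.0001, the smallest the 10000 placements can give). CTCF peaks had a median spacing of 30999 bp, 0.898 of the 34504 ± 721 bp (SD) of uniform placement (permutation p = 0.0001). The next region lay within 5 kb for 27.8% of H2A.V spacings and for 7.68% of CTCF spacings. The lists were called under rules that act on spacing. The filter against the surrounding 10000 bp removed 565 putative CTCF peaks and 0 putative H2A.V peaks, and neighbouring H2A.V windows were stitched. How far these rules shape the contrast between the lists was not tested. Among 100 kb windows, chosen after their counts were seen, 2 held the most CTCF peaks, with 8 each. One, on 2R from 9800001 to 9900000 (dm3), also held 7 H2A.V regions, and 3 of its CTCF peaks overlapped one. The other, on 3R from 12700001 to 12800000, held 0 H2A.V regions. The window with the most H2A.V regions, on 2L from 10300001 to 10400000, held 19 of them and 1 CTCF peak. The widest H2A.V region, on the X from 511825 to 521158, held 0 CTCF peaks.

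The overlap with H2A.V changed along the CTCF list. The order of the lines was used here as a property of the file whose meaning is not recorded. Within each of the 5 large arms the peak numbers rose along the CTCF file (Spearman's rho at least 0.999 across peaks). The H2A.V widths fell along theirs (rho = −0.928 across regions), from a median of 3627 bp in the first of 10 equal parts to 501 bp in the last. Of the early CTCF peaks, 314 of 1230 (25.5%) overlapped any H2A.V region, against 615 of 1229 (50.04%) of the late ones (odds ratio 2.92, two-sided Fisher's exact test, p = 2.08e-36). With the list cut into 10 equal parts, the share was 17.1% (95% Wilson interval 12.9 to 22.3%) in part 1, 14.6% (10.8 to 19.6%) in part 2, 55.7% (49.4 to 61.8%) in part 7 and 39.6% (33.7 to 45.8%) in part 10. On 2L, 2R, 3L and 3R alone it was 26.6% for early and 53.5% for late peaks (odds ratio 3.18, Fisher's exact test, p = 4.11e-33). The first 3 listed CTCF peaks lie on 3L from 14104620 to 14104820, on 2L from 490155 to 490355 and on 3R from 12624514 to 12624714 (dm3), and of these the peak on 2L overlapped an H2A.V region.

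**Figure D3:**
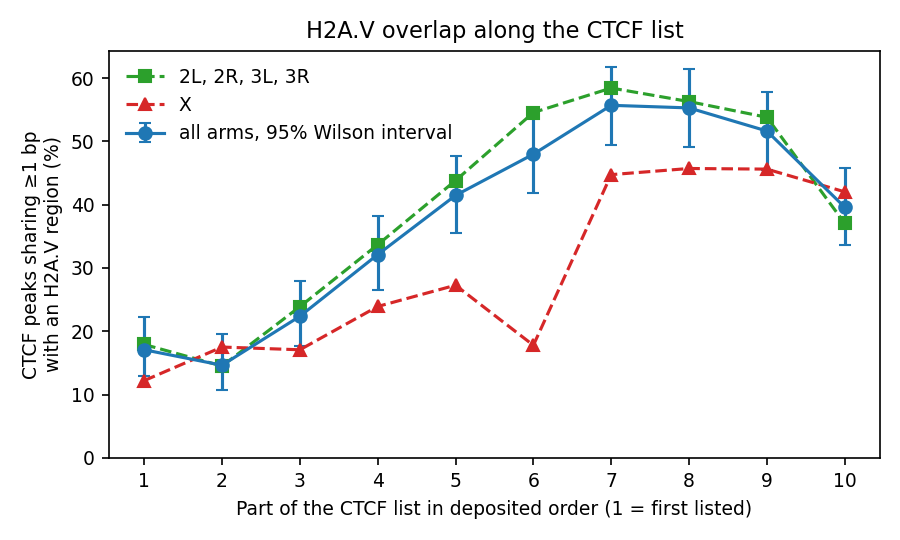
Percent of CTCF peaks that share at least 1 bp with an H2A.V region in 10 equal parts of the CTCF list in deposited order, for all arms (circles, 95% Wilson intervals), for 2L, 2R, 3L and 3R (squares) and for the X (triangles). The share over all arms is 17.1% in part 1, 55.7% in part 7 and 39.6% in part 10.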

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

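The tests that use the deposited order, shifts of 20 to 100 kb or the X against the autosomes were chosen after the data were seen. The edge zones and the comparisons of H2A.V width were not among the planned tests. The other alternatives given in this section were fixed before the data were examined. The overlap of CTCF peaks with H2A.V regions stayed above that of shifted peaks under every alternative run. It was 8.02-fold when at least 50% of the CTCF peak had to be covered, 11.5-fold for midpoints within 500 bp, 7.99-fold against uniform placement, 7.31-fold against shifts of 20 to 100 kb, which keep the regional density, and 7.83 to 8.36-fold when each of 2L, 2R, 3L, 3R, 4 and X was left out in turn. The size of the excess depended most on the part of the lists used, with 4.00-fold among early and 15.1-fold among late entries of both lists in deposited order. These folds have unlike bases, since late H2A.V regions were narrower and shifted peaks hit them less often. Against all H2A.V regions, 25.5% of early and 50.04% of late CTCF peaks overlapped. Shifts of 20 to 100 kb gave 4.88% and 5.46% for these peaks. The excess of CTCF midpoints near H2A.V midpoints was 11.5-fold within 500 bp, 4.83-fold within 2 kb and 4.00-fold within 1 kb among early entries. Clustering on the 5 large arms alone was 0.894 of uniform spacing for CTCF and 0.385 for H2A.V. The higher density of CTCF peaks on the X changed sign without the last 245 peaks of the list, from 3.13 to −1.12 peaks per Mb (permutation test, p = 0.415), a part picked for its X share, so that leaving it out lowers the difference by construction; that of H2A.V regions moved from −0.17 to −2.60 without the last of 10 equal parts (p = 0.268). The lower H2A.V overlap of X-linked CTCF peaks kept its direction among early and late CTCF peaks, with log2 odds ratios of −0.55 for the early (Fisher's exact test, p = 0.0453) and −0.80 for the late (p = 5.23e-05), against −0.50 over all peaks. It was −0.74 without the last of 10 equal parts of the CTCF list (Fisher's exact test, p = 2.87e-05), and in that last part alone the direction was reversed, at 0.30 (p = 0.498). Among early entries, 0 of 13 sequence names differed in share by Fisher's exact test after adjustment, as over all peaks. The planned restriction to higher scores, and the alternatives for start sites, gene lists and motifs, were not run. No paired analysis was possible because each antibody has 1 library. The limits are those of the calling: sites under 37 tags in the CTCF library, and regions under 67 tags per window in the H2A.V library, are not in the lists. Later steps left out more, with 15117 of 18141 putative CTCF peaks removed against the input. The 172723 putative H2A.V peaks led to 3229 listed regions by steps that the header does not itemise. A CTCF peak without an H2A.V region is thus one where no region was listed, which need not be due to depth.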

Other observations

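The tests of regional density and of the H2A.V regions hit by early and late CTCF peaks were fixed before their results were seen, and the others below after. The design has no groups beyond the antibodies, so no biological explanation was tested between groups; the X density and the number of X copies are weighed from the peak lists alone.

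CTCF peaks listed early overlapped H2A.V regions less often than those listed late, 25.5% against 50.04%. The pattern does not rest on the X-linked and unplaced peaks at the end of the list: on 2L, 2R, 3L and 3R alone the share of late peaks exceeded that of early peaks by 26.9 percentage points (SE 2.18), against 24.5 over all peaks. A difference in H2A.V density at 20 to 100 kb from the peaks is argued against too. Shifts over that distance gave 4.88% for the early and 5.46% for the late peaks, a ratio of 1.12. These shifts cannot show a difference in density nearer than 20 kb, which was not tested. If the order follows signal, which no header records, a candidate explanation is that weak CTCF peaks include antibody-independent enrichment at strong H2A.V regions; the mean line percentile of the H2A.V regions hit was 46.0 for late and 47.4 for early CTCF peaks, a difference of −1.38 (SE 1.92, permutation p = 0.471), which leaves it open, as does the lack of a mock ChIP. Sites that differ in kind, with the most occupied CTCF sites away from H2A.V chromatin, may equally give this pattern, and that was not tested.

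X-linked peaks made up 52.4% of the CTCF peaks on the 5 large arms among the last 245 lines and 17.9% among the 2214 lines before (odds ratio 5.05, two-sided Fisher's exact test, p = 3.61e-28). That all of these peaks are calls at random positions is argued against. Of the 119 last X-linked peaks, 42.0% (95% Wilson interval 33.5 to 51.0%) overlapped an H2A.V region, against 4.71% under shifts. The share was 37.0% for the 108 autosomal peaks among the same lines. Random calls among a part of these peaks are not excluded, since the share over all arms was 55.7% in part 7 and 39.6% in part 10. Explanations by signal need the order to follow signal, which no header records. A density of X-linked sites higher by the same factor at every level of signal would give the X the same share throughout the list. The shares of 52.4% and 17.9% argue against it as the source of the concentration. Among early peaks the X had −0.845 per Mb relative to the autosomes (SE 0.83, permutation test, p = 0.409). Whether X density differs among early peaks is thus left open. A bound set earlier on the difference without the last 245 peaks (−1.12) is set aside, because those lines were picked for their X share and leaving them out lowers the difference by construction. A mixed-sex collection carries fewer X copies, so a fold threshold over input could admit X peaks at lower tag counts than autosomal ones; this needs an X share of early peaks below the 18.8% of arm span, and the share was 17.6% (Wilson interval 15.6 to 19.9%), which leaves it open. The X share of H2A.V regions was 14.4% among early regions and 33.1% in the last of 10 equal parts.

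CTCF peaks were in excess over shifts in 2 places, deep inside an H2A.V region and near its edge, with a lower excess between them. For the place deep inside, the widths of the regions alone are argued against: in regions of over 1000 bp, 471 midpoints lay over 500 bp inside, 1.60-fold the count of even placement in the same regions (95% normal interval 1.53 to 1.68). For the higher count at the inner edge than at 250 to 500 bp inside, widths stay open in regions of over 1000 bp. There the outer 250 bp held 55.5% of the 191 midpoints up to 500 bp inside (Wilson interval 48.4 to 62.4%), against 50% under even placement. In regions of 510 to 1100 bp, 45 of 178 midpoints were central (25.3%, Wilson interval 19.5 to 32.1%), against 40% under even placement. This low central share argues against widths alone in that class, which was set after the profile had been seen. The tests in regions of over 1000 bp took the place of a comparison of zones over regions of all widths, in which the mix of widths differs between zones. One hypothesis is that H2A.V windows on both sides of a CTCF site were stitched into 1 region with CTCF at its centre, and a window on one side only left CTCF at the edge. It stays open: regions of 1300 to 2000 bp hold the deep maximum of the profile in their central part by construction, and in regions of over 2000 bp the central share was 41.4% (Wilson interval 35.7 to 47.3%), against 40% under even placement. A comparison of the classes of 1300 to 2000 bp and 510 to 1100 bp was made first and set aside for that reason, and the share in the widest class was already known when it took that place. A gap in H2A.V at the CTCF site itself cannot be seen in stitched regions and stays untested.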
